A study of Mus musculus with 6 samples.

How the data were processed

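REST, RCOR1, RCOR2, RCOR3, SIN3A and SIN3B were each profiled by ChIP-seq in 1 library from E14 mouse embryonic stem cells at passages 15 to 18. Per the labels' protocols, libraries were made with 15 cycles of PCR, fragments of about 250 bp were taken from a gel, and sequencing was done on an Illumina Genome Analyzer. Per the labels, the antibodies against REST and SIN3A recognise the proteins themselves, and a V5 antibody was used on lines expressing a tagged RCOR1, RCOR2, RCOR3 or SIN3B. The label of the SIN3B transgene gives the tag as VG, while its antibody label gives V5. Groups were taken from the sample titles, and each group held 1 library.

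The authors deposited 1 peak list per library with 4 columns, holding chromosome, start, end and a score. The genome build mm8 is taken from the names under which the lists were deposited. The aligner, the peak caller, its control and threshold and the read depth are not given in the sources used here. The meaning of the score that the authors assigned to each peak is likewise not stated, so the score was used to rank peaks within a list. In tests of score ratios, log2 of the RCOR3, SIN3A or SIN3B score over the REST score at the same site was compared between chromosomes, which assumes that a score scales with signal. All starts lay on a 20 bp grid, and whether positions count from 0 or 1 is not stated, so they are printed as deposited. Many peaks share a score, and tied peaks were given the same rank.

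Because the median width of the REST list was under 50 bp, all intervals were set to 400 bp about their midpoints, and an overlap of at least 1 bp counted as shared. This widened nearly all peaks and narrowed the 73 peaks (0.521%) that were wider than 400 bp. The share of each cofactor's peaks at REST peaks was compared with 10000 circular shifts of the REST list along each chromosome within the span of all 6 lists (one-sided). Pairs of cofactor lists were compared in the same way after removing peaks at REST. Shares have exact 95% Clopper-Pearson intervals. Shares were compared between cofactors with Fisher's exact test (two-sided), as were pairs of cofactors among REST peaks and each chromosome's share of a list's peaks away from REST against its share of REST peaks. The number of cofactors per REST peak was compared with 10000 permutations of each cofactor's marks among REST peaks. Score ranks were compared as within-list percentiles with 100000 permutations (two-sided). Adjusted p-values are Benjamini-Hochberg values within each family of 5 cofactors, 10 pairs or 105 combinations of list and chromosome, and the threshold was 0.05. Odds ratios within strata of REST score are Mantel-Haenszel estimates. For other odds ratios, where a count was empty a small constant was added to every count so that a value could be given. No test compares libraries as replicates, since each protein has 1, and intervals cover counting error only.

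Regions named in the text follow a rule written before the data were examined: the 3 highest-scoring peaks of each list, the 10 regions in the most lists ordered by REST rank, the 3 highest REST peaks without a cofactor, and the 3 regions outside REST with the most cofactors. The tests, and the main alternatives, were also fixed before the data were examined. These alternatives were other definitions of a shared peak (overlap of at least 50% of the shorter interval, midpoints within 200 bp, gaps of up to 1000 bp), the better-scoring 50% of every list, lists cut to the 84 peaks of the shortest, a local shift of 10 to 500 kb, merged neighbouring peaks, each chromosome left out in turn, stratification by REST score quartile and a distance of 5000 bp from REST. Alternatives added after seeing the data were the intervals as deposited, wider peaks kept at their width while the others were widened, lists without the crowded stretch of chromosome X, the highest-scoring peaks of each cofactor against all REST peaks with and without that stretch, stratification by REST score decile, chromosome shares over all peaks of a list, and direct comparisons of lists on chromosome X without that stretch. Alternatives used 1000 shifts and 10000 permutations, or 200 shifts for shares at REST of lists left as deposited or with wider peaks kept and for chromosomes left out. For pairs away from REST under those same width alternatives, chance was approximated from the median widths.

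The procedures were tested on simulated data before use. With 15% of the peaks of a list planted at REST peaks, the shift test recovered 15.1 to 15.6% and made the call in 100% of 20 runs for each list. Without planted peaks it made a call in 0 to 5% of runs. These values do not show how often it would call lists whose peaks cluster, as in the crowded stretch of chromosome X. A simulated odds ratio of 4 among 3104 REST peaks came out at 3.91, and one of 1 within strata at 0.999. The latter does not cover an effect of REST score within a stratum. The rank test found scores raised 1.3 times on 1 in 10 of the REST peaks in 100% of 20 runs.

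Position relative to genes, the RE1 sequence motif and gene names of peaks were planned but not analysed here, since no genome or annotation of build mm8 was used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.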

Results

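Binding sites of the transcriptional repressor REST and of 5 of its cofactors were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in E14, a mouse embryonic stem cell line. The cofactors were the CoREST proteins RCOR1, RCOR2 and RCOR3, which bridge REST to histone deacetylases and to the histone demethylase LSD1, and the SIN3 scaffold proteins SIN3A and SIN3B, which also carry histone deacetylases. REST and SIN3A were precipitated with antibodies against the proteins themselves, whereas RCOR1, RCOR2, RCOR3 and SIN3B were precipitated through a V5 epitope tag from E14 lines carrying a tagged transgene. Each protein was represented by 1 library and 1 peak list, so there was no replicate error. All intervals and tests cover counting error and chance overlap, and peaks are not replicates.

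The lists held 3104 peaks for REST, 84 for RCOR1, 459 for RCOR2, 3744 for RCOR3, 1314 for SIN3A and 5318 for SIN3B. The longest list was thus 63.3 times the length of the shortest. The peaks were narrow, with a median width of 40 bp for REST and 60 bp for each cofactor. Each peak carried a score assigned by the authors and used here to rank peaks within that list. REST scores ran from 8 to 1121.33 with a median of 21.04, and the median scores of the cofactor lists lay between 10.93 for SIN3A and 13.26 for SIN3B. Read depth was not given in the sources used here, so the number of peaks was not compared between proteins. All positions are on mouse genome build mm8 as listed by the authors, and no gene annotation of that build was used here.

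To ask how much of the binding of each cofactor lay at REST, the share of its peaks that coincided with a REST peak was determined. Of the RCOR1 peaks, 88.1% (74 of 84, 95% confidence interval 79.2 to 94.1%) lay at a REST peak. The other cofactors had most of their peaks elsewhere. RCOR3 had 25.9% (970 of 3744, 24.5 to 27.3%) at REST, SIN3B 21.9% (1164 of 5318, 20.8 to 23.0%), SIN3A 19.5% (256 of 1314, 17.4 to 21.7%) and RCOR2 17.2% (79 of 459, 13.9 to 21.0%). Shifted REST lists gave mean shares of 0.0846% for RCOR1 and 0.103 to 0.109% for the other 4 cofactors. Every cofactor exceeded its chance share by at least 167-fold, each with an adjusted p = 0.0001 in a one-sided circular-shift permutation test, the smallest value that 10000 shifts can give. Shifted peaks can fall anywhere in the covered span, so chance here means unrelated placement. Away from REST, the 6 pairs of cofactor lists with at least 100 peaks also exceeded it, by 48.6 to 514-fold. A high fold alone is thus not particular to REST.

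**Figure D1:**
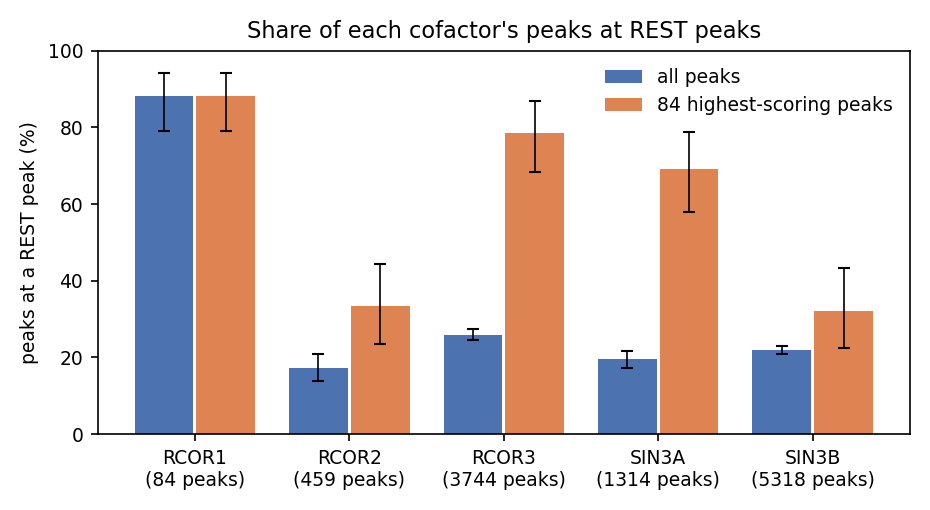
Percentage of the peaks of each cofactor (horizontal axis, list length in brackets) that lay at a REST peak (vertical axis), for all peaks and for the 84 highest-scoring peaks. Bars start at 0 and error bars are exact 95% Clopper-Pearson intervals; RCOR1 has the same value of 88.1% in both because its list holds 84 peaks, while RCOR3 went from 25.9% to 78.6% and SIN3A from 19.5% to 69.0%.

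The share for RCOR1 exceeded that of each of the other 4 cofactors by 62.2 to 70.9 percentage points, with adjusted p from 1.3e-37 to 9.1e-32 in Fisher's exact test. RCOR3 exceeded SIN3A by 6.43 and SIN3B by 4.02 percentage points (adjusted p = 4.7e-06 and 1.6e-05, exact test). For RCOR2, the difference was -8.70 percentage points from RCOR3 (adjusted p = 4.2e-05, exact test) and -4.68 from SIN3B (adjusted p = 0.026, exact test), but the latter no longer passed the threshold with peaks wider than 400 bp kept at their width (-4.06, adjusted p = 0.055, exact test) or with gaps of up to 1000 bp allowed (-3.80, adjusted p = 0.078, exact test). RCOR2 did not differ detectably from SIN3A (adjusted p = 0.30, exact test), nor SIN3A from SIN3B (adjusted p = 0.067, exact test). SIN3A minus SIN3B did pass with intervals as listed by the authors (-3.17, adjusted p = 0.0092, exact test) and without a crowded stretch of chromosome X (-3.03, adjusted p = 0.018, exact test). These differences depended on which peaks of the lists were kept. When only the 84 highest-scoring peaks of each cofactor were set against all REST peaks, the shares were 78.6% for RCOR3, 69.0% for SIN3A, 33.3% for RCOR2 and 32.1% for SIN3B. RCOR1 then exceeded RCOR3 by 9.52 percentage points without passing the threshold (adjusted p = 0.18, exact test), and RCOR3 exceeded SIN3A by the same amount, also without passing (adjusted p = 0.24, exact test). SIN3A exceeded SIN3B by 36.9 percentage points (adjusted p = 5.8e-06, exact test), and RCOR2 minus SIN3A was -35.7 (adjusted p = 1e-05, exact test). With the REST list also limited to its 84 highest-scoring peaks, RCOR1 fell to 36.9% and stood 27.4 percentage points below RCOR3 at 64.3% (adjusted p = 0.0021, exact test). RCOR1 then no longer differed detectably from SIN3A (-5.95, adjusted p = 0.53, exact test) or SIN3B (7.14, adjusted p = 0.46, exact test), while RCOR2 minus SIN3A passed (-23.8, adjusted p = 0.0035, exact test). Of the 84 RCOR1 peaks, 24 lay in the crowded stretch of chromosome X, where REST scores reached only 23.11. These could not meet any of the 84 highest-scoring REST peaks. With both sides limited to 84 peaks, no comparison was made without that stretch.

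Viewed from the REST sites, SIN3B and RCOR3 were the most frequent partners. A SIN3B peak lay at 38.9% of REST peaks (1209 of 3104, 37.2 to 40.7%) and an RCOR3 peak at 32.7% (1016, 31.1 to 34.4%). SIN3A was found at 8.83% (274, 7.85 to 9.88%), RCOR2 at 3.00% (93, 2.42 to 3.66%) and RCOR1 at 2.61% (81, 2.08 to 3.23%). At least 1 cofactor was present at 46.0% of REST peaks (44.2 to 47.8%), and the remaining 1676 REST peaks (54%) had none. The cofactor lists differ in length, so these frequencies are not a measure of occupancy. With only the better-scoring 50% of every list, SIN3B was at 50% and RCOR3 at 46.3% of REST peaks.

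Cofactors gathered at the same REST sites. The commonest combination was RCOR3 with SIN3B and no other cofactor, at 563 REST peaks (18.1%), followed by SIN3B alone at 355 and RCOR3 alone at 187. RCOR3, SIN3A and SIN3B met without RCOR1 or RCOR2 at 148 REST peaks, and all 5 cofactors met at 36. REST scores of these 36 had quartiles of 23.41 and 420.35, so they included weak REST peaks. Of 34 regions of overlapping peaks found in all 6 lists, 9 lay in the crowded stretch of chromosome X. REST scores there reached only 23.11, so the weak peaks among the 36 may lie largely in that stretch. How many did was not counted. At least 2 cofactors were present at 869 REST peaks (28.0%, 26.4 to 29.6%). Random placement of each cofactor's marks among the REST peaks gave a mean of 602 and a highest value of 653 such peaks (permutation p = 0.0001, the smallest value that 10000 permutations can give). For all 5 cofactors together, random placement gave a mean of 0.0262 peaks and at most 2.

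Each of the 10 pairs of cofactors shared REST peaks more often than independent placement would give. Odds ratios ran from 12.2 (8.81 to 16.8) for RCOR3 with SIN3A to 96.3 (56.5 to 164) for RCOR1 with RCOR2, which met at 48 REST peaks against 2.43 under independence. RCOR3 and SIN3B met at 816 REST peaks against 396 under independence, an odds ratio of 17.6 (14.6 to 21.3). The largest adjusted p was 9.3e-25 in Fisher's exact test. Comparing only REST peaks of the same score decile left all 10 pairs past the threshold and lowered the odds ratio to 4.01 (3.21 to 5.02) for RCOR3 with SIN3B, 4.73 for RCOR3 with SIN3A, 7.78 for RCOR1 with SIN3A, 8.84 for RCOR2 with SIN3A, 11.2 for SIN3A with SIN3B and 23.3 for RCOR1 with RCOR2, while it rose to 55.7 for RCOR1 with RCOR3 and 36.1 for RCOR2 with SIN3B. The highest decile alone spanned REST scores from 68.75 to 1121.33. It held 49 of the 81 REST peaks with RCOR1, 49 of the 93 with RCOR2 and 130 of the 274 with SIN3A. For pairs with RCOR1, RCOR2 or SIN3A, REST score was therefore only partly matched. No estimate by decile was made without the crowded stretch of chromosome X. Several odds ratios of pairs with RCOR1 or RCOR2 also moved by more than 1.5 times with the definition of a shared peak, the score threshold or a crowded stretch of chromosome X left out, as did that of SIN3A with SIN3B with intervals as deposited (9.96), and RCOR1 with RCOR3 ranged from 9.94 to 276. The value of 276 came without that stretch, where all 62 REST peaks with RCOR1 also had RCOR3. A count was then empty, so 276 depends on the added constant and does not measure a size.

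The strongest REST sites carried the most cofactors. In the highest decile of REST scores, 98.1% of REST peaks had SIN3B (95.8 to 99.3%), 96.5% RCOR3 (93.8 to 98.2%), 41.8% SIN3A (36.3 to 47.5%), and 15.8% each RCOR1 and RCOR2 (11.9 to 20.3%). In the lowest decile these shares were 9.32% (6.33 to 13.1%) for SIN3B, 8.04% (5.27 to 11.6%) for RCOR3, 3.54% (1.78 to 6.24%) for SIN3A, 1.93% (0.711 to 4.15%) for RCOR2 and 1.61% (0.524 to 3.71%) for RCOR1. SIN3B and RCOR3 increased over the upper 5 deciles of REST score, whereas RCOR1 and RCOR2 stayed at or below 2.26% from decile 4 to decile 9. The lower deciles include the crowded stretch of chromosome X, where REST scores reached at most 23.11, within decile 6. Of the REST peaks with RCOR1, 62 of 81 lay outside that stretch, and of those with RCOR2, 74 of 93. The others all fell in deciles 1 to 6, so the low-decile shares of RCOR1 and RCOR2 rest in large part on that stretch.

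**Figure D2:**
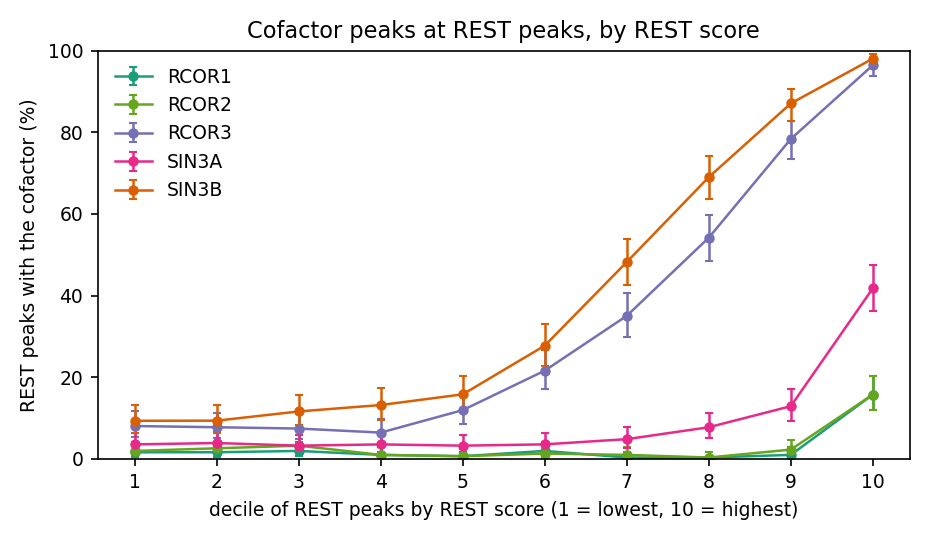
Percentage of REST peaks with a peak of each cofactor (vertical axis) in 10 groups of REST peaks of nearly equal size (deciles) ordered by REST score (horizontal axis). REST peaks of the crowded stretch of chromosome X are included. Points are shares of 310 or 311 REST peaks and error bars are exact 95% Clopper-Pearson intervals; SIN3B and RCOR3 reached 98.1% and 96.5% in the highest decile, and RCOR1 and RCOR2 both reached 15.8%.

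REST peaks with a given cofactor ranked higher by REST score than those without it. The difference in mean percentile was 37.2 for SIN3B, 37.1 for RCOR3, 28.1 for SIN3A, 23.6 for RCOR1 and 20.3 for RCOR2 (each adjusted p = 1e-05, two-sided permutation test, the smallest value that 100000 permutations can give). Without the crowded stretch of chromosome X the differences were 37.5 for RCOR1 and 32.3 for RCOR2. The median REST score was 13.63 at REST peaks with no cofactor, 28.45 with 1, 50.97 with 2 and 209.66 with 5 (quartiles 23.41 and 420.35). Across REST peaks, which are not independent replicates, the score correlated with the number of cofactors at a Spearman rho of 0.671 (permutation p = 1e-05, the smallest possible).

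In turn, peaks of RCOR2, RCOR3, SIN3A and SIN3B at REST ranked higher within their own lists than those elsewhere. The difference in mean percentile was 21.5 for RCOR3, 19.7 for SIN3A, 14.3 for SIN3B (each adjusted p = 1.7e-05, two-sided permutation test) and 11.8 for RCOR2 (adjusted p = 0.001, permutation test). With the crowded stretch of chromosome X left out, the difference for RCOR2 fell to 8.49 (adjusted p = 0.032, permutation test). It was then 21.7 for RCOR3, 19.2 for SIN3A and 14.2 for SIN3B. In the highest quintile of scores, 56.6% of RCOR3 peaks (53 to 60.2%), 43.0% of SIN3A peaks (36.9 to 49.2%), 35.6% of SIN3B peaks (32.7 to 38.6%) and 30.4% of RCOR2 peaks (21.3 to 40.9%) lay at REST. For RCOR1, with 10 peaks away from REST, the difference was -0.135 percentile points (adjusted p = 0.99, permutation test), and so few peaks could show only a large difference.

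Where cofactors meet outside REST sites was examined after removing all peaks at REST. RCOR2 met RCOR3, and SIN3A met SIN3B, far more often than other pairs of well-filled lists met. Of the 380 RCOR2 peaks away from REST, 192 (50.5%, 45.4 to 55.7%) coincided with an RCOR3 peak, 28 (7.37%, 4.95 to 10.5%) with a SIN3B peak and 11 (2.89%, 1.45 to 5.12%) with a SIN3A peak. Of the 1058 SIN3A peaks away from REST, 487 (46.0%, 43.0 to 49.1%) coincided with SIN3B and 68 (6.43%, 5.03 to 8.08%) with RCOR3. RCOR3 and SIN3B shared 276 of the 2774 RCOR3 peaks away from REST (9.95%, 8.86 to 11.1%). The fold over chance was 514 for RCOR2 with RCOR3 and 281 for SIN3A with SIN3B, and between 48.6 and 72.8 for the other 4 of these 6 pairs.

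**Figure D3:**
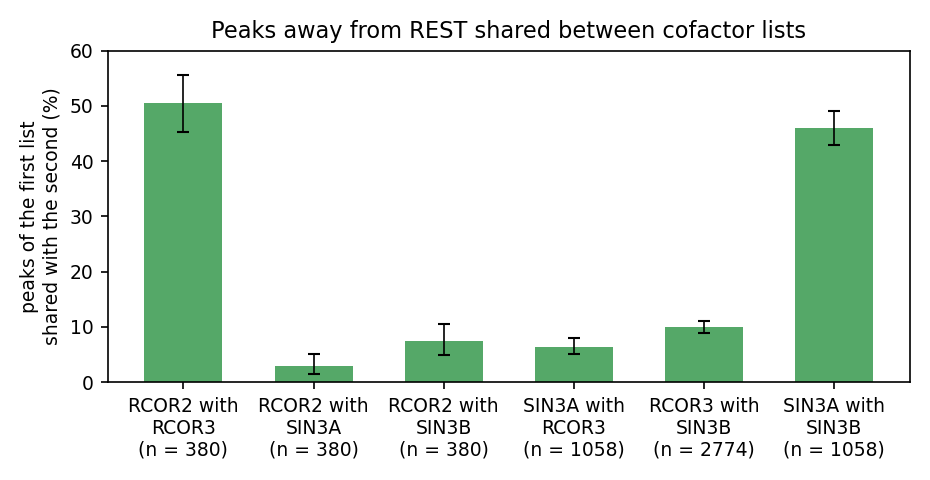
Percentage of the peaks of the first-named list that coincided with a peak of the second (vertical axis), among peaks away from REST, for the 6 pairs of lists with at least 100 such peaks (horizontal axis, number of peaks of the first list as n). Bars start at 0 and error bars are exact 95% Clopper-Pearson intervals; RCOR2 with RCOR3 stood at 50.5% and SIN3A with SIN3B at 46.0%, and the other 4 pairs between 2.89% and 9.95%.

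All 10 pairs passed the threshold away from REST, with adjusted p from 0.00012 to 0.0041 in one-sided circular-shift permutation tests. The 4 pairs with RCOR1 rested on 10 RCOR1 peaks, of which 4 met RCOR2, 3 SIN3A, 3 SIN3B and 1 RCOR3. RCOR1 with SIN3A and RCOR1 with SIN3B went to 0 shared peaks without the crowded stretch of chromosome X, and also when no REST peak was allowed within 5000 bp, whereas RCOR1 with SIN3A rose from 30% to 50% with gaps of up to 1000 bp. Without that stretch RCOR1, then with 5 such peaks, went from 40% to 20% with RCOR2 and from 10% to 20% with RCOR3, and RCOR2 with SIN3A went from 2.89% to 1.88%. With the narrow intervals as listed by the authors, RCOR1 met RCOR2 at 18.5%, SIN3B at 14.8% and SIN3A at 11.1%, SIN3A met SIN3B at 26.6% and RCOR3 met SIN3B at 5.60%.

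The chromosomes held cofactor peaks unevenly. Chromosome 8 held 5.28% of REST peaks (164 of 3104) but 16.4% of SIN3A peaks away from REST (174 of 1058, odds ratio 3.53, 2.81 to 4.42), 13.2% of those of RCOR2 (50 of 380, odds ratio 2.72, 1.94 to 3.80) and 9.63% of those of SIN3B (400 of 4154, odds ratio 1.91, 1.58 to 2.31). RCOR3 went the other way on chromosome 8, with 2.42% (67 of 2774, odds ratio 0.444, 0.332 to 0.592), and was nearly missing from chromosome 9, with 0.577% (16 of 2774) against 5.86% of REST peaks (odds ratio 0.0931, 0.0557 to 0.156). Counting all RCOR3 peaks, those at REST included, the odds ratio on chromosome 9 was 0.173. At the REST peaks of chromosome 9, RCOR3 was present at 14.8% (27 of 182) against 34.9% on the autosomes other than 8 and 9, while SIN3B was present at 40.7% against 38.5%. RCOR3 was more frequent on chromosome 10 (6.45% against 4.35%) and chromosome 17 (6.85% against 4.38%). Fisher's exact test passed the threshold for 10 of 105 combinations of list and chromosome, 6 higher and 4 lower than REST, with adjusted p of 6.6e-32 for RCOR3 on chromosome 9 and 3.9e-25 for SIN3A on chromosome 8.

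**Figure D4:**
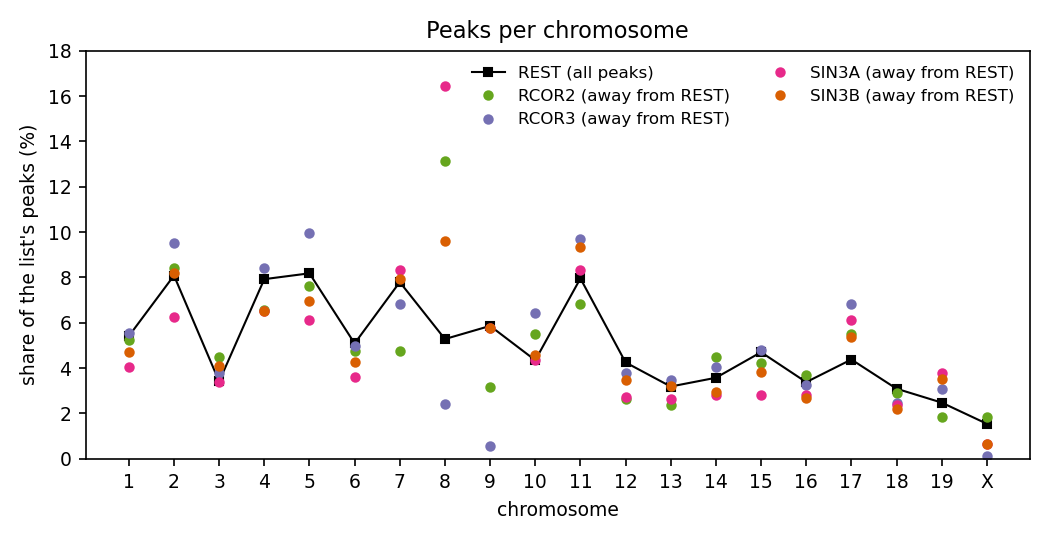
Percentage of peaks (vertical axis) on each autosome and on chromosome X (horizontal axis) for all REST peaks (squares joined by a line) and for the peaks away from REST of RCOR2, RCOR3, SIN3A and SIN3B (circles); RCOR1, with 10 such peaks, is left out. On chromosome 8, SIN3A stood at 16.4% and RCOR3 at 2.42% against 5.28% for REST, and on chromosome 9 RCOR3 stood at 0.577% against 5.86%.

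On chromosome X, which held 1.55% of REST peaks, RCOR1 had 6 of its 10 peaks away from REST (adjusted p = 8.6e-08, exact test), SIN3B had 0.674% (adjusted p = 0.0043, exact test) and RCOR3 had 0.108% (odds ratio 0.0689, adjusted p = 5e-09, exact test). Over all RCOR3 peaks, the odds ratio on chromosome X was 0.290, and away from REST without a crowded stretch it was 0.0460. The calls for RCOR1 and SIN3B ended without that stretch of 38.2 kb at X:165313931-165352151, at adjusted p = 0.19 and 0.38 in the exact test. In all, 9 combinations of list and chromosome passed without it, not all of them among those reported with it. Counting peaks at REST too, chromosome X held 24 of 3080 REST peaks outside the stretch and 26 of 5294 for SIN3B. It held 0 of 1292 for SIN3A, 1 of 437 for RCOR2 and 2 of 3729 for RCOR3. RCOR3 was thus not the only list with few peaks there. In that stretch lay 24 peaks each of REST, RCOR1 and SIN3B, 22 each of RCOR2 and SIN3A and 15 of RCOR3. They made up 28.6% of all RCOR1 peaks (19.2 to 39.5%), 4.79% of RCOR2 peaks and 1.67% of SIN3A peaks, but at most 0.773% of the REST, RCOR3 and SIN3B lists. REST scores in the stretch were low, with a median of 11.85 at percentile 23.7 of the list, whereas the median percentile of the peaks there was 87.8 for SIN3A, 75.2 for RCOR2, 68.6 for SIN3B, 64.9 for RCOR1 and 49.3 for RCOR3.

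**Figure D5:**
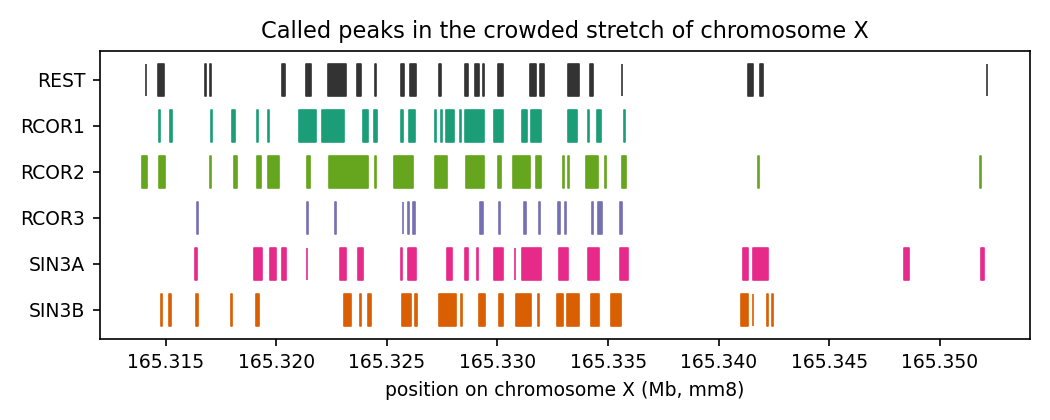
Map of the 38.2 kb stretch of chromosome X, with position in megabases on build mm8 (horizontal axis) and 1 row per list (vertical axis). Each block is a listed peak drawn to its width; the rows hold 24 peaks for REST, 24 for RCOR1, 22 for RCOR2, 15 for RCOR3, 22 for SIN3A and 24 for SIN3B.

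At single sites, REST and the cofactors shared their strongest peaks. The region 7:6014211-6014271 held the highest-scoring peak of the REST (1121.33), RCOR2 (52.01), RCOR3 (378.03), SIN3A (151.54) and SIN3B (253.67) lists and the second-ranked peak of RCOR1 (56.98). At 19:4989131-4989211, REST ranked 4 (score 696.98), RCOR1 4, RCOR2 3, RCOR3 3, SIN3A 2 and SIN3B 2. At 8:14072691-14072751, REST ranked 2 (838.04), SIN3A 3 and SIN3B 3, whereas RCOR2 ranked 436 of 459. At 14:62635791-62635851, RCOR3 ranked 2 (237.52), RCOR1 3 and REST 6, and at 15:77947151-77947231 REST ranked 3 (704.68) and RCOR3 4. The regions 4:139531191-139531271, 15:84657311-84657471, 4:150448451-150448971, 15:72395971-72396031 and 9:21700851-21701271, with REST ranks of 5, 7, 8, 9 and 10, also had peaks of all 5 cofactors. At 9:21700851-21701271, on the chromosome where RCOR3 peaks were scarce, RCOR3 ranked 32, RCOR2 4 and RCOR1 8. In all, 34 of 10282 merged regions appeared in all 6 lists, 9 of them in the crowded stretch of chromosome X, which also gave the second-ranked RCOR2 peak (X:165334011-165334531, score 37.69).

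Some strong sites were not shared. The highest-scoring RCOR1 peak, X:102389451-102389731 with a score of 168.7, was in no other list. RCOR1 was expressed from an introduced construct, and whether the reads of this peak came from the chromosome or from the construct was not tested, so the peak is not shown to be a binding site, though it is 1 of the 10 RCOR1 peaks away from REST. The strongest REST peaks without any cofactor were 12:102951731-102951771 (score 87.12, REST rank 193), 6:113809151-113809191 (65.19, rank 356) and 7:33252291-33252611 (64.6, rank 362), so every REST peak ranked above place 193 had at least 1 cofactor. Overlapping intervals of all lists were also merged into regions, and 7251 regions held no REST peak, of which 935 lay in at least 2 cofactor lists. Among these, those with the most cofactors were 16:96250071-96250571, with RCOR2, RCOR3, SIN3A and SIN3B, X:165319011-165319351 in the crowded stretch, with RCOR1, RCOR2, SIN3A and SIN3B, and 2:119238391-119238591, with RCOR2, RCOR3 and SIN3B. A merged region can join a REST peak to a cofactor peak that does not itself overlap REST, as it did for the RCOR2 peak X:165330711-165331451 in the crowded stretch, which overlapped peaks of all 4 other cofactors.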

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

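The tests of peak numbers in the chromosome X stretch, of odds on chromosomes 8 and 9, of filled stretches, of score ratios on all autosomes and of chromosome X without its crowded stretch were chosen after the results were seen, and that of alignment was chosen after the peak positions in the stretch, and that of score ratios on chromosome 9 after summaries of RCOR3 scores by chromosome, had been seen.

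Pairs of cofactor lists that departed from REST in opposite directions on a chromosome were compared directly with Fisher's exact test on their peaks away from REST. The pairs were picked for those departures in the same peaks, so the odds give their size and are no separate evidence. On chromosome 8, where RCOR3 was scarce, the odds of a peak relative to RCOR3 were 6.12 for RCOR2 (4.17 to 8.98), 7.95 for SIN3A (5.94 to 10.6) and 4.31 for SIN3B (3.31 to 5.60). On chromosome X, the odds for RCOR1 were 1386 relative to RCOR3 (254 to 7567) and 221 relative to SIN3B (59.1 to 826), both from 6 RCOR1 peaks. Without the crowded stretch of chromosome X, 1 of 5 RCOR1 peaks away from REST remained on that chromosome, and the odds were 693 (36.6 to 13106, adjusted p = 0.0072, exact test) and 51.6 (5.52 to 482, adjusted p = 0.025, exact test), so both then rest on 1 peak, X:102389451-102389731, which is not shown to be a binding site since its reads were not told apart from those of the RCOR1 construct.

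The RCOR3 list was short on chromosomes 8 and 9, and a lost part of the list was argued against, since RCOR3 peaks filled 10 of 10 equal stretches of each chromosome. On chromosome 9, REST peaks of the same score decile carried an RCOR3 peak at 0.10 times the odds of other autosomes in its proximal and in its distal part, with a highest upper 95% limit of 0.305, and among the strongest decile of REST peaks log2 of the RCOR3 score over the REST score differed from other autosomes by -0.70 ± 0.088 (SE, 20 against 270 sites, permutation p = 0.0001, the smallest possible). Chromosome 9 was the 1 call past the threshold among 38 such tests of RCOR3 and SIN3B on the 19 autosomes (adjusted p = 0.0038, permutation test, difference -0.69 against all other autosomes), so the shortage may reflect lower signal along the whole chromosome in this library or higher signal in its control. On chromosome 8 the odds ratio of RCOR3 at REST peaks was 0.352 (0.205 to 0.605) over the whole chromosome and 0.292 (0.1496 to 0.570) in the distal part. In the proximal part, with 50 REST peaks, it was 0.526 with an upper limit of 1.32. Whether the shortage spans the whole chromosome thus cannot be told. SIN3A and SIN3B went the other way on chromosome 8, at 2.19 (1.25 to 3.84) and 1.93 (1.296 to 2.865) over the whole chromosome. In the distal part they stood at 2.43 (1.305 to 4.51) and 2.86 (1.75 to 4.67). In the proximal part SIN3A stood at 1.46 (0.411 to 5.17) and SIN3B at 0.951 (0.478 to 1.89). A gain of SIN3A or SIN3B along the whole chromosome was therefore not shown. Copy number in the cells used, the control, the authors' processing and a difference in binding itself stay open for chromosomes 8 and 9, as the design has 1 library per protein and no control library was used here.

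Peaks crowded at the far end of chromosome X in all 6 lists, where RCOR1 had 24 of its 84 peaks. Their numbers per list differed by a ratio of only 1.6, against 88.2 elsewhere, which is consistent with background picked up by every library. Peaks of different lists also lay closer together than after random shifts within the stretch (mean of the median nearest distances 218 bp against 984 bp, permutation p = 5e-04, the smallest that 2000 shifts can give), which binding at the same points predicts but sequence that maps unevenly could also give. Neither explanation was excluded, and no control library was used here to separate them.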

How the results depend on the processing

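Alternatives without the chromosome X stretch, with intervals as deposited, with wider peaks kept at their width, with the highest-scoring peaks of each cofactor against all REST peaks, stratified by REST score decile, or over all peaks of a list were chosen after the results were seen. Of 488 alternative values for 68 results under 24 settings, 436 were counted as unchanged. They kept their direction and side of the threshold, stayed within the error of the reported value, or were counts of passing tests. Such counts could differ, as for differences in the share at REST, with 6 to 9 pairs past the threshold against 8 reported. All 70 alternative shares of cofactor peaks at REST, all 90 alternative odds ratios of cofactor pairs at REST and all 30 alternative differences in REST score percentile were counted as unchanged. The size of these values was not judged. A share at REST had only to exceed chance, at most 0.109% for the reported lists, and could hardly fail. The alternative shares ranged from 36.9 to 94.05% for RCOR1, 13.9 to 33.3% for RCOR2 and 21.8 to 86.7% for RCOR3. For SIN3A they ranged from 15.6 to 73.3%, and for SIN3B from 18.8 to 32.1%. The odds ratio of RCOR1 with RCOR3 ranged from 9.94 to 276. The latter, without the chromosome X stretch, depends on the constant added for an empty count. Where a value changed the cause was not tested, and taking the highest-scoring peaks changes list length and score threshold together. With 1 library per protein and no depth given in the sources used here, peaks below each list's threshold cannot be assessed. No paired analysis was possible because each protein has 1 library.

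With at least 50% of the shorter interval overlapped, or with midpoints within 200 bp, which is the same for intervals of 400 bp, 30.9% of REST peaks had RCOR3, 37.15% SIN3B, 44.2% at least 1 cofactor and 26.4% at least 2. With the better-scoring 50% of every list, the shares were 46.3% for RCOR3, 11.65% for SIN3A, 50% for SIN3B, 61.8% for at least 1 cofactor and 36.55% for at least 2. With intervals as deposited they were 1.93% for RCOR1, 2.19% for RCOR2, 26.3% for RCOR3, 6.64% for SIN3A, 32.2% for SIN3B, 40.2% for at least 1 and 21.2% for at least 2, and without the chromosome X stretch 2.01% for RCOR1 and 2.40% for RCOR2.

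Of the 80 alternative differences in the share at REST, 60 kept their direction and side of the threshold. With gaps of up to 1000 bp, RCOR2 minus SIN3B was -3.80 percentage points (adjusted p = 0.078, exact test) and the RCOR1 percentile difference turned to 5.95. With wider peaks kept at their width, RCOR2 minus SIN3B was -4.06 (adjusted p = 0.055, exact test). With the 84 highest-scoring peaks of every list, RCOR1 minus RCOR3 was -27.4 and RCOR2 minus SIN3A -23.8, both past the threshold, and RCOR1 minus SIN3A -5.95, RCOR1 minus SIN3B 7.14, RCOR2 minus SIN3B -10.7 and SIN3A minus SIN3B 13.1, all short of it. With the 84 highest-scoring cofactor peaks against all REST peaks, RCOR1 minus RCOR3 and RCOR3 minus SIN3A were both 9.52 and RCOR2 minus SIN3B 1.19, all short of the threshold, and RCOR2 minus SIN3A was -35.7 and SIN3A minus SIN3B 36.9, both past it. With that choice and no X stretch (60 peaks) they were 5 for RCOR1 minus RCOR3, -6.67 for RCOR2 minus SIN3B and 13.3 for RCOR3 minus SIN3A, short of the threshold, and -48.3 for RCOR2 minus SIN3A and 41.7 for SIN3A minus SIN3B, past it. SIN3A minus SIN3B passed the threshold at -3.03 without the X stretch and at -3.165 with intervals as deposited.

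Away from REST, RCOR1 with SIN3A and RCOR1 with SIN3B both fell to 0% without the X stretch and with no REST peak within 5000 bp, and no longer passed. On chromosome X, the odds ratio of RCOR1 was 31.8 without the stretch and 17.4 with peaks within 10 kb merged, and that of SIN3B 0.617 and 0.641, and 0.604 over all peaks of the list, all short of the threshold. Over all RCOR1 peaks, those in the stretch included, the odds ratio was 27.0 and passed (adjusted p = 2.3e-21, exact test).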

Other observations

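The tests of V5 background, of places that give a peak in any library and of a further list where a pair meets were chosen after the results were seen, and the score correlations and the strongest sites away from REST were not planned.

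Where a cofactor peak lay at a REST peak outside the crowded stretch of chromosome X, the midpoints almost coincided. The median distance was 20 bp for RCOR1, RCOR3 and SIN3B and 30 bp for RCOR2 and SIN3A, and between 81.1% (RCOR2) and 90.6% (SIN3B) of such REST peaks had the cofactor midpoint within 100 bp. At these shared sites, scores rose and fell together across lists. Spearman rho across peaks, which are not independent replicates, was 0.592 for REST with RCOR3 (1003 peaks), 0.581 for REST with SIN3B (1192 peaks), 0.401 for REST with SIN3A (258 peaks) and 0.347 for REST with RCOR2 (74 peaks). Among pairs of cofactors it ran from 0.454 for RCOR2 with SIN3A to 0.658 for RCOR1 with SIN3A.

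Strong cofactor sites were also found away from REST. SIN3B had peaks at 8:87950151-87950191 (score 117.71, rank 6 of 5318), 10:76702931-76702971 (115.23, rank 7) and 5:139714271-139714311 (111.91, rank 10), each shared with 1 other list. RCOR3 had peaks at 11:117719891-117719931 (78.62, rank 18 of 3744) and 7:48996091-48996131 (66.07, rank 25), each shared with 1 other list. The strongest SIN3A peak away from REST, 8:74539991-74540251 (49.54, rank 9 of 1314), was in no other list. For RCOR2, the strongest such peaks outside chromosome X were 2:152107771-152107811 (24.12, rank 9 of 459) and 14:44354011-44354051 (22.61, rank 13), each shared with 1 other list. These sites were chosen after their values were seen.

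The meeting of RCOR2 with RCOR3, and of SIN3A with SIN3B, away from REST was weighed against technical explanations. The circular shifts kept each list's number of peaks on each chromosome, so the uneven chromosomes were already part of the chance shares. Without chromosomes 8, 9 and X, SIN3A met SIN3B at 45.0% of its peaks away from REST, and RCOR2 met RCOR3 at 56.9%. The meeting was thus not confined to those chromosomes. This comparison could decide no more, since 816 of the 1058 SIN3A peaks lay on the others and the fall predicted for uneven chromosomes was out of reach. Background of the V5 antibody, or places that give a peak in any library, would not as the whole cause favour these pairs, but the values against them only restate the shares that prompted the question: 182 RCOR2 peaks met RCOR3 alone and 18 SIN3B alone, 449 SIN3A peaks met SIN3B alone and 30 RCOR3 alone, and the lowest fold over chance was 0.0947 of the highest over the 6 pairs with at least 100 peaks (the prediction had named 10 pairs, and those with RCOR1 were left out because it had 10 such peaks). A test that does not restate them was undecided, as SIN3B lay at 5.21% of RCOR2 peaks with RCOR3 and 9.57% of those without (odds ratio 0.519, 0.233 to 1.16, p = 0.12, exact test), and RCOR3 at 7.80% of SIN3A peaks with SIN3B and 5.25% of those without (1.53, 0.931 to 2.50, p = 0.10, exact test). A part played by either stays open, and no biological explanation was tested.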
